A study of Citrus maxima with 2 samples.

How the data were processed

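RNA was measured by sequencing in 2 libraries made from developing floral buds of pummelo (Citrus maxima) at the stage of petal and stamen primordia. One library came from the male sterile cybrid line G1+HBP and the other from the male fertile line HBP. A cybrid is a plant made by fusing cells so that its nucleus and its cytoplasm come from different parents. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was enriched on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers before adaptors were ligated. No treatment was applied. Each label describes a pool of tissue, and each line had 1 library, so the spread between biological replicates is unknown for every value given here. The series' design text speaks of a larger number of pools than the 2 libraries, and others were not analysed here. The 2 used are titled HBP-St and G1+HBP-St and may not stand for other pools.

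The 1 table used has the columns that Cuffdiff writes for genes, per the file headers. TopHat2 2.0.8b, Cufflinks 2.1.1 and Cuffdiff 2.1.1 are named in the submitters' processing notes. The genome build, the annotation and the options of these programs are not given in the sources used here. The chromosome positions below are those of that unnamed build and cannot be taken as positions in a pummelo genome. For each locus the authors deposited an FPKM value per library, that is, fragments per kilobase of transcript per 1000000 fragments. The same table holds the authors' p-value and q-value (a p-value adjusted for multiple testing) for each locus, per the file headers. These compare 2 libraries, not the 2 lines. The log2 ratio and test statistic of the table were not used, since the ratio is unreadable where G1+HBP is listed at 0. Coordinates are given as the table prints them, and whether its start positions count from 0 or from 1 is not given in the sources used here. No value column lacked a sample (0 columns).

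The table had 30721 loci, of which 29268 carried at least 1 gene identifier and 1453 carried none. It pairs no identifier with a gene name or product, and no table of names was used here. The gene lists fixed before the data were examined (floral organ identity, tapetum and pollen wall, carpel, photosynthesis, respiration, hormones, cell cycle and others) could therefore not be matched to any locus, and none is reported. No sequence in the table is labelled as mitochondrial or chloroplast, so the planned description of organelle-encoded genes could not be made either. For the same reason the loci are described by position, and only 4 identifiers are named. They follow a rule fixed before the data were examined: among loci with an FPKM of at least 5 in at least 1 library, the 2 identifiers with the largest positive difference (G1+HBP minus HBP) and the 2 with the largest negative one. The rule was read as covering only loci with a gene identifier. Every other locus or window described by position was chosen after its values were seen. Most were loci called in the authors' table. The rest were a tested locus between 2 called ones, 5 of the 10 loci with a gene identifier and the highest FPKM, a short locus with a large difference, and the windows with the highest and lowest medians.

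Differences were computed as log2(FPKM + 1) in G1+HBP minus log2(FPKM + 1) in HBP. This scale understates the change of loci with low values. Loci with an FPKM of at least 1 in at least 1 library were counted as expressed, and those differing by at least 1 on the log2 scale were counted as 2-fold apart. No test of difference was run, since none is possible with 1 library per line. The table has no column of calls, so loci with an authors' q-value of at most 0.05 are named "called" below. These 64 loci are also the first 64 rows of the table, ahead of all others. The lowest p-value in the table is 5e-05, held by 53 loci, which sets the lowest q-value at 0.0175.

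The number of reads per library is not in the table, so the depth is unknown and no counting interval is given. The ratios of FPKM hold some information on the relative depth. Among loci above 0 in both libraries, the commonest ratio of FPKM (G1+HBP over HBP) was 0.996, shared by 74 loci within 0.00005 on the log2 scale. Their median FPKM in HBP was 6.04, and 66 of the 74 had no gene identifier. Another 25 loci had this ratio times 2, and 19 had it times 0.5. This pattern arises where reads were counted whole, and 1 read was then worth nearly the same FPKM in both libraries. It was read mainly from loci without an identifier. An FPKM of 0 can be a failed estimate, so such loci are described as listed at 0 and are given no fold.

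Lists of called loci were compared with 10000 random lists of tested loci of the same size, matched on mean log2(FPKM + 1) in 20 bins. Their percentiles describe these libraries and are not tests between the lines. A called neighbour was another called locus within 100 kb on the same sequence, a measure chosen after the positions of the called loci were seen. The correlation of neighbouring loci and the medians of windows of 50 loci were compared with orders shuffled within chromosomes. The alternatives were pseudocounts of 0.1 and 5, centring, scaling to a sum of 1000000, other filters on FPKM and a stricter q-value. Others, chosen after seeing the data, scaled both libraries to the mean of their sums, left out loci without a gene identifier, short loci or loci listed at 0, or changed the distance to a neighbour. The scripts used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. They were tested on simulated data for the 30721 loci of the comparison, with 200 loci changed by known amounts. The simulation held counting noise alone, at an assumed depth, and changed only loci with a mean FPKM of at least 5. All 50 loci raised by 2 on the log2 scale and 96% of the 50 lowered by 1.5 were found 2-fold apart. So were 0% of unchanged loci with a mean FPKM of at least 5. This checks the scripts and gives no rate of false differences for the real libraries, whose depth and variation between plants are unknown.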

Results

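Gene expression was measured by RNA sequencing in floral buds of 2 pummelo lines at the stage of petal and stamen primordia, the male sterile cybrid G1+HBP and the male fertile HBP. Each line had 1 pooled library, so no value below has a replicate error and no difference has a replicate check. In HBP, 21859 of the 30721 loci had an FPKM above 0 and 18221 reached an FPKM of 1. In G1+HBP, 22201 loci were above 0 and 18507 reached an FPKM of 1. The 18908 loci that reached an FPKM of 1 in at least 1 library had a median FPKM of 14.5 in HBP and 14.9 in G1+HBP. Judged from the commonest ratio of FPKM, 1 read was worth nearly the same FPKM in both libraries (a ratio of 0.996). That ratio was shared by 74 loci, 66 of them without a gene identifier, and the total number of reads is unknown.

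The first comparison asked how far the transcripts of the male sterile cybrid differed from those of its fertile type. The profiles were alike at most loci. Across the expressed loci, log2(FPKM + 1) correlated with a Pearson r of 0.968 and the FPKM with a Spearman rho of 0.971 between the libraries. These correlations are across genes, which are not independent replicates. The 13929 loci with an FPKM of at least 5 in both libraries differed by a median of -0.02 on the log2 scale (G1+HBP minus HBP), with a 5th percentile of -0.45 and a 95th of 0.52.

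A total of 563 loci were at least 2-fold higher in G1+HBP and 247 were at least 2-fold lower, together 4.28% of the expressed loci. The higher loci made up 69.5% of the 810. When each library was instead scaled to the mean of the 2 sums of FPKM, the median of loci at an FPKM of 5 in both moved to -0.18, and the counts were 429 higher and 349 lower, or 55.1% higher. Scaling each library to a sum of 1000000 gave 213 higher and 148 lower (59.0% higher). This setting also lowers every FPKM relative to the pseudocount of 1. The sums behind both scalings came mostly from loci under 100 bases (63.4% in HBP and 69.2% in G1+HBP). Setting the median of loci at an FPKM of 5 in both to 0 gave 580 higher and 237 lower (71.0% higher). With the FPKM as deposited, higher loci outnumbered lower ones at each level of expression. Of the loci whose larger FPKM lay between 1 and 5, 216 were higher and 106 lower. Between 5 and 20 there were 187 higher and 71 lower, between 20 and 100 there were 110 and 45, and above 100 there were 50 and 25. Of the 1442 expressed loci without a gene identifier, 16.0% were 2-fold apart, with 134 higher and 96 lower. Of the 17466 with one, 3.32% were apart, with 429 higher and 151 lower.

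**Figure D1:**
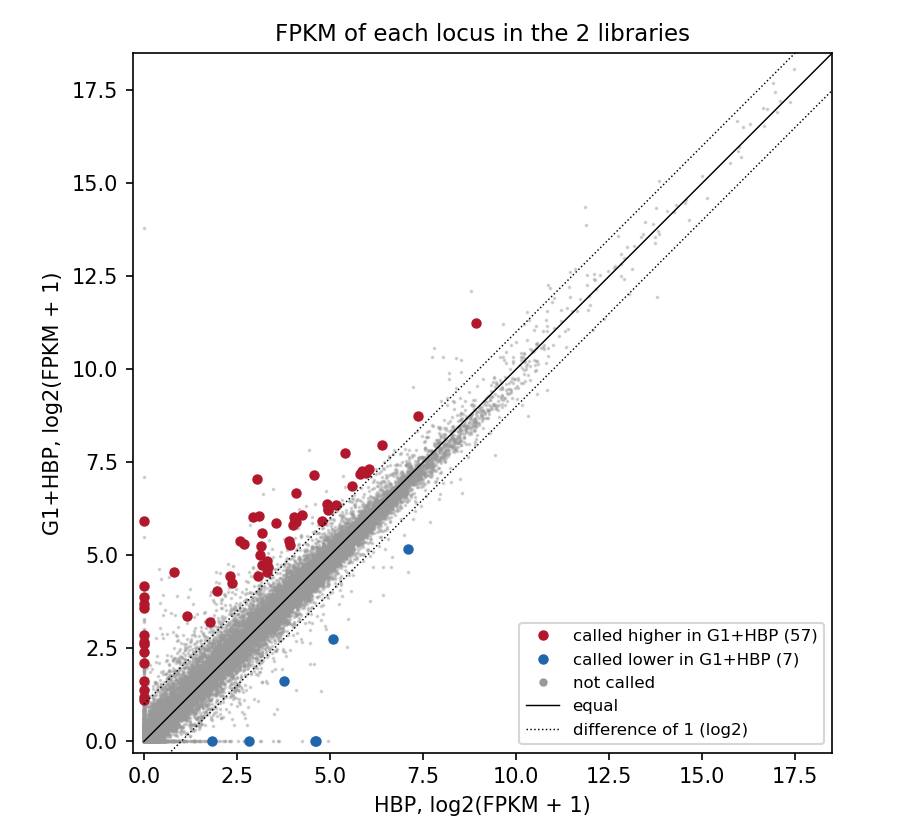
Each point is a locus, with log2(FPKM + 1) in the HBP library on the horizontal axis and in the G1+HBP library on the vertical axis. Red points are the 57 loci called higher in G1+HBP and blue points the 7 called lower in the authors' deposited table (q of at most 0.05). The dotted lines mark a difference of 1 on the log2 scale. Points on either axis are loci listed at 0 in 1 library, or in both libraries at the origin.

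In the authors' deposited table, 64 of the 18569 tested loci had a q-value of at most 0.05, of which 57 were higher in G1+HBP and 7 were lower. A total of 55 carried a gene identifier, 51 of them higher and 4 lower. The other 9 had none, and 8 of these 9 were listed at 0 in 1 of the libraries. Among the 43 called higher that were above 0 in both libraries, the ratio of FPKM ran from 2.24 to 29.6 with a median of 3.69. Their median FPKM was 14.3 in HBP and 59.3 in G1+HBP. At an unadjusted p of at most 0.05, the authors' deposited table had 473 loci higher and 139 lower, which is 3.30% of the tested loci. These p-values compare the 2 libraries and hold no estimate of the variation between plants.

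The highest ratio among the called loci was at chromosome 6, 9231007 to 9234353, a locus with a gene identifier whose FPKM was 0.753 in HBP and 22.3 in G1+HBP (29.6-fold, q = 0.0175 in the authors' deposited table). A locus at chromosome 8, 4406563 to 4407517, followed with an FPKM of 7.16 in HBP and 131 in G1+HBP (18.3-fold). The locus next to it, at 4437665 to 4438721, had an FPKM of 6.67 and 64.9 (9.72-fold). On chromosome 5, the locus at 25719137 to 25721993 had an FPKM of 7.54 in HBP and 65.4 in G1+HBP (8.67-fold). On chromosome 2, the locus at 6628217 to 6631077 had 4.98 and 40.8 (8.19-fold). On chromosome 1, the locus at 20628684 to 20631566 had 1.23 and 9.32 (7.58-fold). On chromosome 7, the locus at 3941575 to 3943519 had 5.47 and 38.6 (7.05-fold). On chromosome 8, the locus at 16493766 to 16494733 had 15.9 and 101 (6.40-fold). On chromosome 3, the locus at 24006210 to 24007688 had 22.7 and 143 (6.27-fold). The other loci called higher and above 0 in both libraries had lower ratios. The most abundant called locus, at chromosome 5, 16670263 to 16670543, had no gene identifier and spanned 280 bases. Its FPKM was 489 in HBP and 2430 in G1+HBP (4.97-fold).

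Only 3 of the 7 loci called lower in G1+HBP were above 0 in both libraries. The locus at chromosome 7, 7439930 to 7442585, had an FPKM of 12.6 in HBP and 2.08 in G1+HBP, 6.08-fold higher in HBP. At chromosome 3, 24833674 to 24835448, the FPKM was 32.6 in HBP and 5.71 in G1+HBP, 5.71-fold higher in HBP. The third, at chromosome 5, 28549747 to 28641867, had 136 in HBP and 35.2 in G1+HBP, 3.86-fold higher in HBP. It shares its printed coordinates with other rows of the table, so its exact place within these bounds is not known, and it is the 1 called locus for which this holds.

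**Figure D2:**
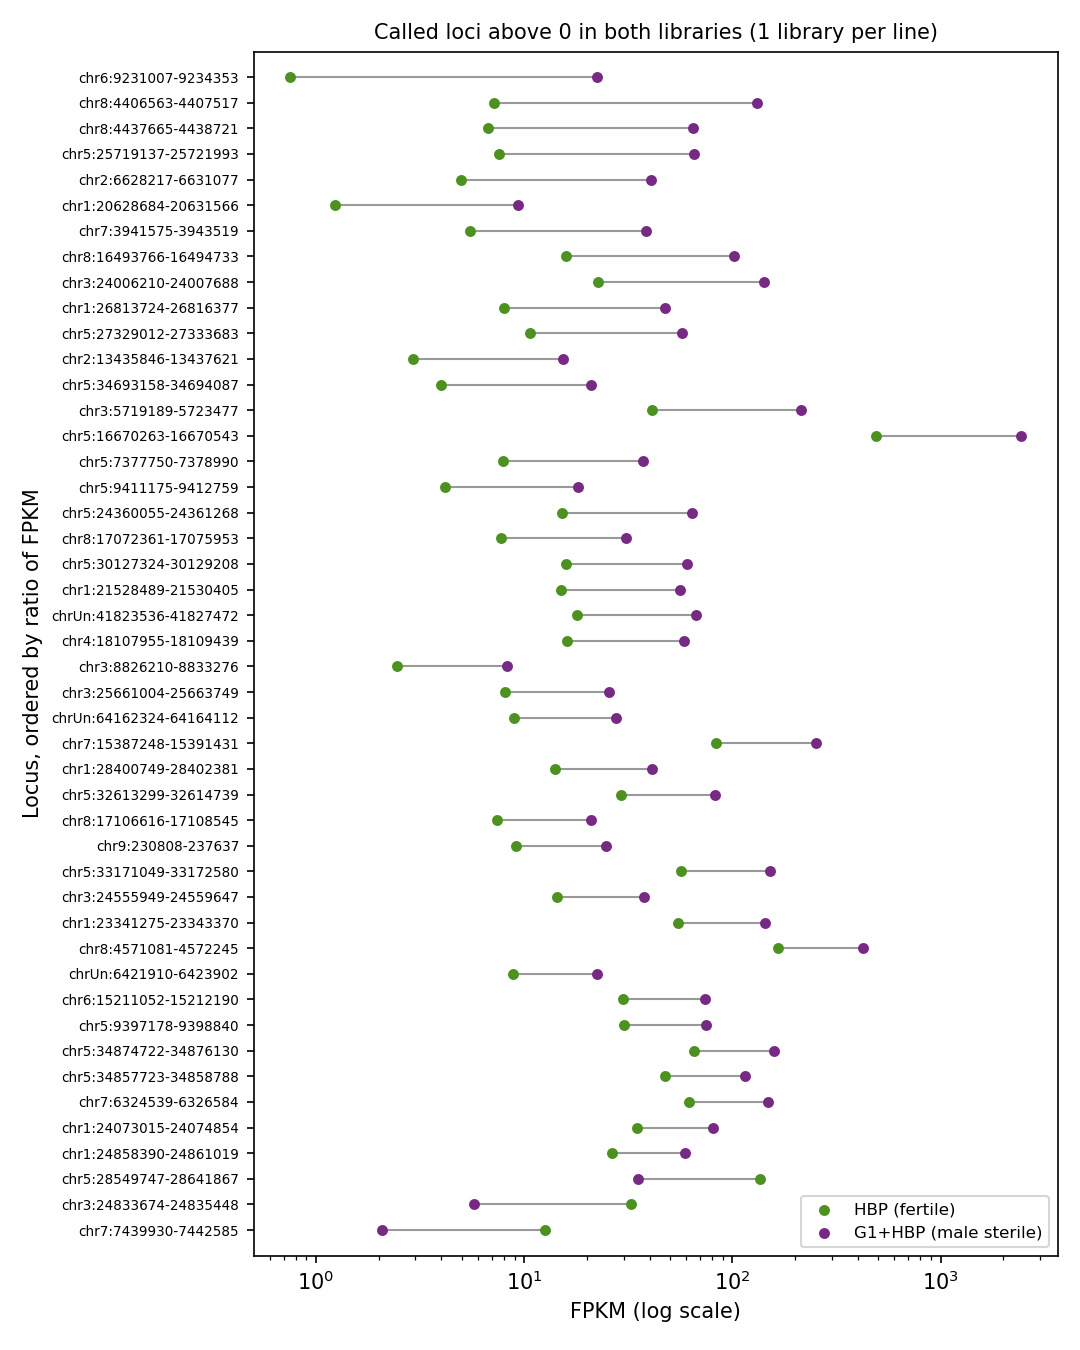
The 46 called loci above 0 in both libraries, one per row and ordered by their ratio, with the FPKM on a logarithmic axis. Green points are the HBP library and purple points the G1+HBP library, with 1 library each and no error bars. The purple point lies to the right in 43 rows and to the left in 3.

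Loci listed at 0 in 1 library made up 18 of the 64 called. In HBP 14 were listed at 0, of which 9 carried a gene identifier. The highest of these 9 in G1+HBP was at chromosome 7, 24723758 to 24724318, with an FPKM of 11.1. The next were on unplaced sequence, at 53515988 to 53518259 with an FPKM of 6.26 and at 73246907 to 73248290 with 5.42. The highest without an identifier, also on unplaced sequence at 88486479 to 88486651, had an FPKM of 59.5. In G1+HBP 4 called loci were listed at 0. A pair of these lay side by side without an identifier at chromosome 7, 16957754 to 16960077, with an FPKM of 6.04 and 23.9 in HBP. Another without an identifier was at chromosome 2, 13259000 to 13259303, with an FPKM of 23.4 in HBP. The one with an identifier, at chromosome 7, 6897066 to 6899364, had an FPKM of 2.59 in HBP. Among all tested loci, 75 were listed at 0 in 1 library, 55 of them in HBP and 20 in G1+HBP. Of these 75, 18 were called, against 64 (these 18 included) of all 18569 tested loci. Such loci have an extreme ratio by definition, so their higher share of calls is no separate finding. Some of them were near the floor: the lowest of the 9 with an identifier listed at 0 in HBP, at chromosome 2, 7547083 to 7548858, had an FPKM of 1.18 in G1+HBP.

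The identifiers with the largest differences on the log2(FPKM + 1) scale were not among the called loci. The largest positive difference was that of orange1.1t05643, on unplaced sequence at 88876662 to 88877031, which was listed at 0 in HBP and had an FPKM of 43.9 in G1+HBP (q = 0.522 in the authors' deposited table). The next was orange1.1t02452, on unplaced sequence at 37514074 to 37517657, with an FPKM of 0.316 in HBP and 23.7 in G1+HBP (75.1-fold, q = 0.999 in the authors' deposited table). The largest negative difference was that of Cs9g12520, at chromosome 9, 10909024 to 10909192, a span of 168 bases. Its FPKM was 29.8 in HBP and it was listed at 0 in G1+HBP (q = 0.975 in the authors' deposited table). The next was orange1.1t01902, on unplaced sequence at 30198776 to 30254823, with an FPKM of 18.1 in HBP and listed at 0 in G1+HBP (q = 0.999 in the authors' deposited table).

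By chromosome, the median difference of the expressed loci stayed between -0.02 (chromosome 4) and 0.02 (unplaced sequence) on the log2 scale. Chromosome 5 held the most called loci, 14 higher and 1 lower among 2371 tested. Its 15 called loci lay at percentile 99.05 of random lists matched on mean expression, which had a median of 8. Chromosome 8 held 8 called loci, all of them higher, among 1332 tested (percentile 93.0, median of random lists 5). Chromosome 7 held 8, of which 4 were higher and 4 lower. Chromosome 4 held 1 among 1369 tested, at percentile 2.95. These are 4 of the 10 sequences compared in this way.

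Called loci also lay close to each other. Of the 64, 14 had another called locus within 100 kb, in 7 pairs, where random lists matched on mean expression had a median of 4 and at most 16. In each pair both loci differed in the same direction, 6 pairs higher and 1 lower in G1+HBP. Since 57 of the 64 called loci were higher, most pairs would share a direction wherever they lay. The lower pair is the one on chromosome 7 described above, whose loci lie side by side without an identifier and may not be separate transcripts. The pair on chromosome 8 at 4406563 to 4438721 is described above, and a called locus lay 132 kb further on at 4571081 to 4572245, with an FPKM of 165 in HBP and 424 in G1+HBP (2.57-fold). A second pair on chromosome 8, at 17072361 to 17108545, had an FPKM of 7.72 and 7.44 in HBP and 31.0 and 20.9 in G1+HBP. A pair at chromosome 8, 9231119 to 9271290, was listed at 0 in HBP, with 4.33 and 2.104 in G1+HBP. The tested locus between them had an FPKM of 18.7 in HBP and 18.9 in G1+HBP. On chromosome 5, the pair at 9397178 to 9412759 had an FPKM of 30.1 and 4.17 in HBP and 74.4 and 18.1 in G1+HBP. The pair at chromosome 5, 34857723 to 34876130, had 47.6 and 65.2 in HBP and 115 and 158 in G1+HBP. The pair at chromosome 5, 24360055 to 24367291, joined a locus with an identifier (15.2 in HBP and 63.9 in G1+HBP) to one without (listed at 0 and 13.7).

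**Figure D3:**
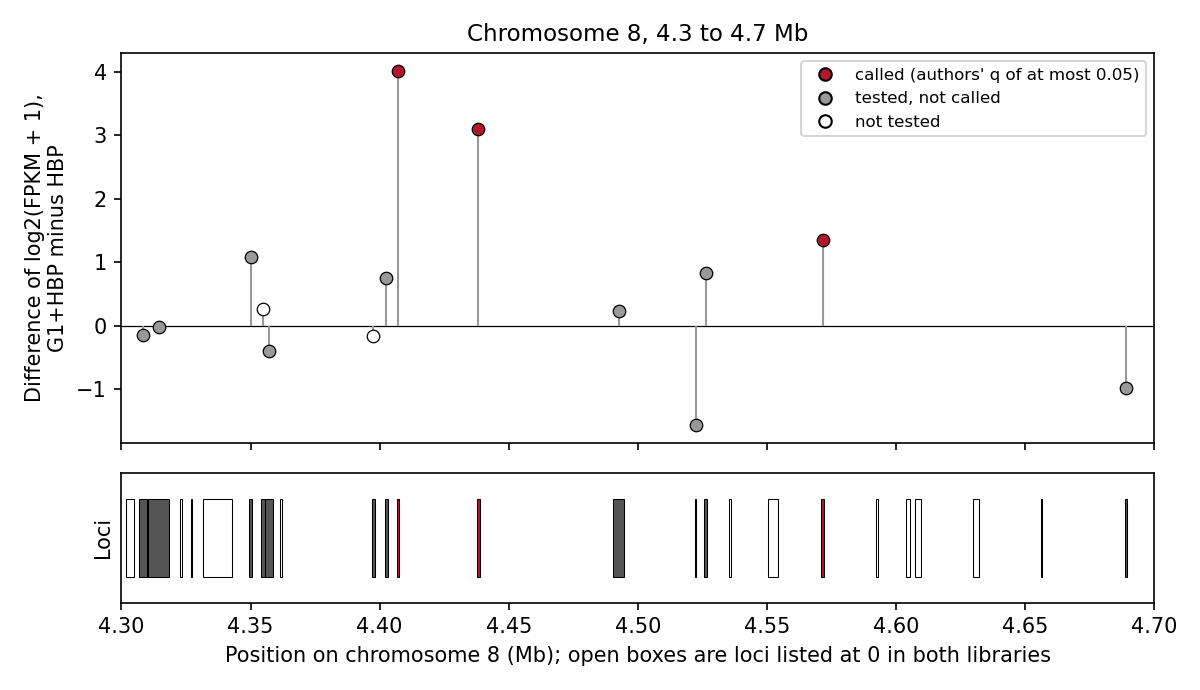
The upper panel gives the difference of log2(FPKM + 1), G1+HBP minus HBP, of loci on chromosome 8 between 4.3 and 4.7 Mb, and the lower panel their positions. Red marks the 3 called loci. In the upper panel grey points are the 9 tested and not called and white points those not tested. Loci listed at 0 in both libraries are left out there. In the lower panel open boxes are the loci listed at 0 in both libraries, and dark grey boxes are all other loci not called. The tested loci that were not called lay between -1.56 and 1.08, on either side of 0.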

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

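Several alternatives were chosen only after the results were seen: scaling to the mean of the sums, those with annotated loci, loci of at least 300 bases or loci above 0 in both libraries, and the other distances. The direction of the excess (more loci higher than lower in G1+HBP) held under every setting that left any loci. The number of loci 2-fold apart depended on the pseudocount, with 889 higher and 420 lower at 0.1 and 199 higher and 80 lower at 5, because it sets how far low values are shrunk. A minimum FPKM of 5 left 347 higher and 141 lower. Scaling to a sum of 1000000 gave 213 higher and 148 lower, but it combines an offset between the libraries with a larger pseudocount relative to the values. Scaling to the mean of the sums, which changes the offset alone, gave 429 higher and 349 lower, both within 1.5 times the main counts. With annotated loci only, 151 were lower. Centring, no filter on low values, tested loci only and spans of at least 300 bases kept both counts within 1.5 times. No filter moved nothing, since a locus below an FPKM of 1 in both libraries cannot be 2-fold apart on this scale. Of the called loci, 0 higher and 0 lower remained at q of at most 0.01, because the lowest q-value in the table is 0.0175. With annotated loci only, 4 were called lower, and with loci above 0 in both libraries only, 3 were called lower. The called loci with a called neighbour numbered 8 when loci listed at 0 were left out (percentile 99.3 of random lists) and between 10 and 18 under the other 3 settings. The 4 named identifiers kept their direction under each of their 3 settings, and 8 of these 12 values moved, all with the pseudocount. The gene list medians and the organelle-encoded genes have no value under any setting, since no identifier has a name and no sequence is labelled as an organelle. No paired analysis was possible because each line has 1 library. Leaving out a library was not possible for the same reason. The depth is unknown, which limits what an FPKM of 0 can show.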

Other observations

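The tests of scaling, depth, short loci, pools, chance positions and shared reads below were chosen only after the results were seen, and so was the count of called neighbours itself. The bound for the correlation of neighbouring loci was set before that correlation was computed. Among loci with a gene identifier, the highest FPKM was at chromosome 8, 12032419 to 12034348, with 103804 in HBP and 94523 in G1+HBP. The next, at chromosome 6, 12935837 to 12936074, had 5672 in HBP and 6439 in G1+HBP. A pair of loci close together on chromosome 5 followed, at 16159934 to 16161067 (4879 in HBP and 5934 in G1+HBP) and at 16140201 to 16141497 (4396 and 6046). The largest difference among the 10 highest was at chromosome 1, 22698329 to 22698996, where the FPKM was 2604 in HBP and 1552 in G1+HBP, a difference of -0.75 on the log2 scale. No locus among these 5 was called in the authors' deposited table.

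Loci without an identifier held 73.2% of the summed FPKM in HBP and 77.5% in G1+HBP. The 106 loci spanning under 100 bases alone held 63.4% and 69.2%. The highest single value, 277369 in G1+HBP, belonged to such a locus. The sums were 2965977 in HBP and 3344321 in G1+HBP, so scaling by the sum follows these short loci. One short locus, at chromosome 9, 10939626 to 10939680, was listed at 0 in HBP and had an FPKM of 14103 in G1+HBP, with a q-value of 0.695 in the authors' deposited table.

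Of the loci called in the authors' deposited table, 57 were higher and 7 lower in G1+HBP. A difference in depth is argued against by the FPKM worth of 1 read, whose ratio was 0.996 (66 of the 74 loci that gave it had no identifier). Among called loci with an identifier, a span of at least 300 bases and values above 0 in both, 42 of 45 (93.3%) were higher. The excess in the called list therefore did not rest on short or unannotated loci. These 45 belong to the same list, whose counts had been seen, so they are no separate support for the excess. Scaling to the mean of the sums lowered the share of higher loci among those 2-fold apart from 69.5% to 55.1% (429 higher and 349 lower). It moved the median of loci at an FPKM of 5 in both from -0.02 to -0.18. With that median set to 0, the share was 71.0% (580 higher and 237 lower). The lowest ratio among the 43 called higher and above 0 in both was 2.24. A shift as small as that of the median would not reverse their direction, but this was bound to hold. All 64 called loci were at least 2-fold apart on the log2 scale. The authors' calls could not be remade under either scaling, so the part of scaling in the number of calls stays open. A difference between these pools that is not due to the line, such as bud stage or tissue make-up, cannot be told apart from an effect of the line with 1 library per line, and the biological difference that the design names, male sterile cybrid against fertile type, stays open and untested.

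The called loci lay near each other more often than random lists, with 14 having a called neighbour at percentile 99.965 of the 10000 lists. As many were found in 0.06% of the lists, and in 1.3% when only loci above 0 in both libraries were used. The count was chosen after the positions were seen and the lists were matched on mean expression alone. These values therefore cannot decide whether the positions arose by chance. A strong relation between neighbours across the whole genome is argued against, since the correlation of neighbouring loci's differences, called loci left out, was 0.047 over 10190 loci. That correlation is across genes and lay above the highest of 1000 shuffled orders, 0.032, so a slight relation is there. Noise in the differences lowers such a correlation, and whether the relation bears on the called pairs was not tested. Reads shared between near-identical neighbours stay open, since the gap between the log2 ratios of a pair, in the 4 pairs with values above 0, ran from 0.0092 to 0.91 with a median of 0.66 and no sequence was compared here.

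It was also asked whether a stretch of a chromosome was shifted as a whole. The highest median of 50 neighbouring loci was 0.14, at chromosome 7, 8393433 to 9100404, and 80 of 200 shuffled orders had one as high. The lowest was -0.17, at chromosome 4, 9626565 to 10929026, and 101 of 200 shuffled orders had one as low. No such shift was detectable at this resolution.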
